A study of Homo sapiens with 2 samples.

How the data were processed

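The cells were PC9, a human lung adenocarcinoma line driven by an activating mutation of the EGFR receptor. Per the labels, they were transduced with lentivirus carrying sgRNAs at an infection rate of about 40%, with polybrene at 8 ug/ml, and selected with puromycin at 1 ug/ml. The labels give day 8 for the experiment and also day 7 for an initial harvest, so the day the cells come from is uncertain. The sgRNAs were read by direct capture beside a 10x Genomics 3' gene expression library, so that each cell carries both a transcriptome and the identity of its sgRNA. The series lists 2 samples, an sgRNA capture library and a gene expression library of the same cells, and both were deposited in 1 joint matrix. The labels speak of knockout and also of dCas9, a Cas9 that binds without cutting, and of knockdown, so the kind of perturbation is left open here. They name 4 target families, whereas the matrix holds sgRNAs against 6 genes (MYC, PGAM1, CTNNB1, JUN, ATF4 and CTCF) and 4 non-targeting control sgRNAs. They also describe several sgRNAs per vector, whereas at most 3.90% of the cells holding an sgRNA of a gene held 2 or more sgRNAs of that gene. The sgRNAs were therefore treated as delivered singly. The sgRNA sequences and their cut or binding sites were not analysed here.

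The deposited values are raw counts: whole-number counts of unique molecular identifiers (UMIs) per feature and cell barcode. They were made with Cell Ranger 6.1.2 per the file headers, on the genome build hg38 per the submitters' processing notes. Alignment settings, filters before deposit and the removal of doublets are not given in the sources used here. The matrix holds 10847 cell barcodes, 36601 genes and 36 sgRNAs, with 136071789 gene UMIs and 158909 sgRNA UMIs. The smallest barcode holds 500 gene UMIs. Of the 36601 gene identifiers, 36366 were matched in the reference gene table, whose assembly, GRCh38.p14, is the same build as hg38 and gave the positions of the targeted genes. No column of another series was present.

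Before the data were examined, the cell filter, the sgRNA rule, the tests, 31 gene lists, the rule for named genes and the alternatives were fixed. Cells needed at least 1000 gene UMIs, at least 500 genes and at most 20% mitochondrial UMIs. This removed 705 barcodes, 522 of them for mitochondrial UMIs alone and 183 for few UMIs or genes, and kept 10142 cells. A cell was assigned to its most abundant sgRNA when that sgRNA had at least 5 UMIs and at least 80% of the cell's sgRNA UMIs. This assigned 5556 cells (54.8%). No sgRNA UMI was found in 1121 cells, and 9.96% of cells held at least 5 UMIs of sgRNAs of 2 or more targets, from doublets or double infection. The doublet caller Scrublet marked 1 cell (0.00986%) and was judged not to have worked. Assignment to a single sgRNA therefore served as the guard against doublets. Doublets of cells with the same sgRNA remain, as do doublets of an assigned cell with a cell of few or no sgRNA UMIs. So do 93 assigned cells that held at least 5 UMIs of sgRNAs of 2 targets.

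The unit of the tests of genes and gene lists between targets and controls was the sgRNA. Later checks that pool cells over sgRNAs have ranges over genes or random lists, not over sgRNAs. Gene counts were summed over the cells of each sgRNA, and 34 sgRNAs with at least 20 cells entered, holding 5530 cells. These were 4 control sgRNAs, 2 of MYC, 4 of PGAM1 and 6 each of CTNNB1, JUN, ATF4 and CTCF, and their sums ranged from 267726 UMIs (MYC) to 6430143 UMIs (CTNNB1). The sums were compared with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test, with TMM scaling, edgeR's own filter on low counts (11570 genes kept) and 1 fit for all targets. Each target was contrasted with the controls, and p-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. The biological coefficient of variation was 4.64%. All sgRNAs came from 1 pool and 1 culture, so the p-values measure only the spread between sgRNAs, which may be technical. Standard errors (SE) are those of the log2 fold change. Levels are CPM, the counts of a gene divided by the total gene count of the sgRNA and scaled to a common total, given as mean ± SD over sgRNAs.

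Gene lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, which gave 24 lists and 144 pairs of list and target. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the pairs. List tests without the targeted gene and without each control sgRNA in turn were chosen after seeing the data. Fry asks whether a list's genes move, on balance, in 1 direction, and does not compare them with other genes. Each target's own transcript is always named. Beyond that, the named genes are the 12 largest increases and the 12 largest decreases among genes past the threshold. Those had to have the same direction in every sgRNA and a mean of at least 10 CPM. Where fewer than 10 genes passed, the 10 with the smallest p are named. Up to 4 list members past the threshold are named per list, and per cluster the 10 genes of largest fold at 50 CPM or more. Genes with near-identical copies, such as AKR1C1 and AKR1C2, the HSPA1A pair, the metallothioneins and ribosomal proteins with processed pseudogenes, are uncertain where Cell Ranger's counting could split or drop shared reads. The strand setting is not given in the sources used here, so antisense genes such as THUMPD3-AS1 are uncertain too.

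Cells were clustered with scanpy 1.11.5 (Leiden, igraph 0.11.9) on 2000 variable genes, 30 components and 15 neighbours at resolution 0.5, and cell cycle phases were scored from the G1/S and G2/M lists. Folds between a cluster and the other cells were computed on CPM with 1 added. Shares and pooled levels have exact 95% intervals (binomial for shares of cells, Poisson for counts), which cover counting error only. A list's place among 10000 random lists of the same size and expression is a description, not a test. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

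The test was tried on simulated counts with the real means and library sizes, with 200 genes changed per target. The least expressed of the tested genes were left out when these were drawn, so the recovery rates do not cover them. Of the genes changed 2-fold, 93% were recovered in the ATF4 simulation, 81% for PGAM1, 95% for CTNNB1, 92% for JUN, 94% for CTCF and 37% for MYC. Of those changed 1.41-fold, 59% were recovered for ATF4, 41% for PGAM1, 63% for CTNNB1, 57% for JUN, 57% for CTCF and 12% for MYC. Between 1 (MYC) and 8 (JUN and CTNNB1) false calls arose per simulation. The alternatives were DESeq2 1.42.0, its size factors, no filter on low counts, looser (3 UMIs and 60%) and stricter (10 UMIs and 90%) sgRNA rules, no cell filter and at most 10% mitochondrial UMIs. Further ones were G1-scored cells alone, a fit of the target and the controls alone, each sgRNA left out in turn, and other cluster settings.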

Results

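The data were 1 pooled culture of PC9 cells, a human lung adenocarcinoma line with an activating EGFR mutation, read by single-cell RNA sequencing with capture of the sgRNA in each cell. The matrix held 136071789 gene UMIs and 158909 sgRNA UMIs in 10847 cell barcodes. The 10142 cells that passed the filter had between 1011 and 39824 gene UMIs, with a median of 12239.5 UMIs, 3385 genes and 10.6% mitochondrial UMIs. A single sgRNA was assigned to 5556 cells. Of these, 700 cells (12.6%, exact 95% binomial interval 11.7 to 13.5%) carried non-targeting control sgRNAs. CTNNB1 sgRNAs were in 1552 cells (27.9%), CTCF sgRNAs in 1182 (21.3%), ATF4 sgRNAs in 859 (15.5%), JUN sgRNAs in 836 (15.05%) and PGAM1 sgRNAs in 333 (5.99%). MYC sgRNAs were in 94 cells (1.69%, interval 1.37 to 2.07%), and 2 of the 4 MYC sgRNAs, with 68 cells, had enough cells to be tested. Per the labels, non-targeting sgRNAs made up 5% of the library, but those labels also name 4 target families, not the 6 genes found here. How abundant each sgRNA was in the virus pool is not given in the sources used here, so no growth effect is read from these shares.

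The first question was whether each set of sgRNAs lowered the transcript it was named for. PGAM1, the phosphoglycerate mutase of glycolysis (ENSG00000171314, GRCh38.p14 chromosome 10, 97426191 to 97433444), was 3.15-fold lower with PGAM1 sgRNAs, at 72.9 ± 19.8 CPM (SD, n = 4 sgRNAs) against 210.8 ± 4.49 CPM with controls (n = 4). Its log2 fold change was -1.66 ± 0.092 (SE; edgeR adjusted p = 8.5e-24), and all 4 sgRNAs lay between 54.1 and 99.87 CPM. CTNNB1, which encodes beta-catenin (ENSG00000168036, chromosome 3, 41199505 to 41240443), was 1.87-fold lower with CTNNB1 sgRNAs, at 26.5 ± 8.32 CPM (n = 6) against 50.3 ± 7.95 CPM. Its log2 fold change was -0.90 ± 0.14 (edgeR adjusted p = 9.97e-05; lower in 6 of 6 sgRNAs). ATF4, the transcription factor of the integrated stress response (ENSG00000128272, chromosome 22, 39520559 to 39522686), was 1.42-fold lower with ATF4 sgRNAs, at 258 ± 45.7 CPM (n = 6) against 366 ± 14.9 CPM. Its log2 fold change was -0.51 ± 0.070 (edgeR adjusted p = 6.6e-07; lower in 6 of 6 sgRNAs). JUN, a subunit of the AP-1 transcription factor (ENSG00000177606, chromosome 1, 58780791 to 58784047), did not pass, with 64.9 ± 10.6 CPM (n = 6) against 75.2 ± 3.85 CPM and a log2 fold change of -0.14 ± 0.096 (edgeR adjusted p = 1.0; lower in 5 of 6 sgRNAs). CTCF, the insulator protein of chromatin loops (ENSG00000102974, chromosome 16, 67562526 to 67639177), did not pass either, with 35.2 ± 7.72 CPM (n = 6) against 42.1 ± 4.73 CPM and a log2 fold change of -0.18 ± 0.11 (edgeR adjusted p = 0.88; lower in 5 of 6 sgRNAs). The lowest CTCF value, 21.3 CPM, was that of CTCF sgRNA 3. MYC, a transcription factor of growth (ENSG00000136997, chromosome 8, 127735434 to 127742951), was not lower in cells labelled with MYC sgRNAs. It stood at 139.6 and 87.4 CPM with the 2 tested sgRNAs against 70.7 ± 4.62 CPM, with a log2 fold change of 0.62 ± 0.25 (edgeR adjusted p = 0.48). The kind of perturbation is left open here, and a knockout need not lower a transcript, whereas a knockdown would. These levels alone therefore do not show whether the JUN, CTCF and MYC sgRNAs acted. The CTNNB1 call was lost under the stricter sgRNA rule (-0.76, edgeR adjusted p = 0.058), in cells with at most 10% mitochondrial UMIs (-0.82, adjusted p = 0.26) and in G1-scored cells (-0.79, adjusted p = 0.050). The sign for JUN turned in cells with at most 10% mitochondrial UMIs (0.065) and that for CTCF in G1-scored cells (0.24).

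**Figure D1:**
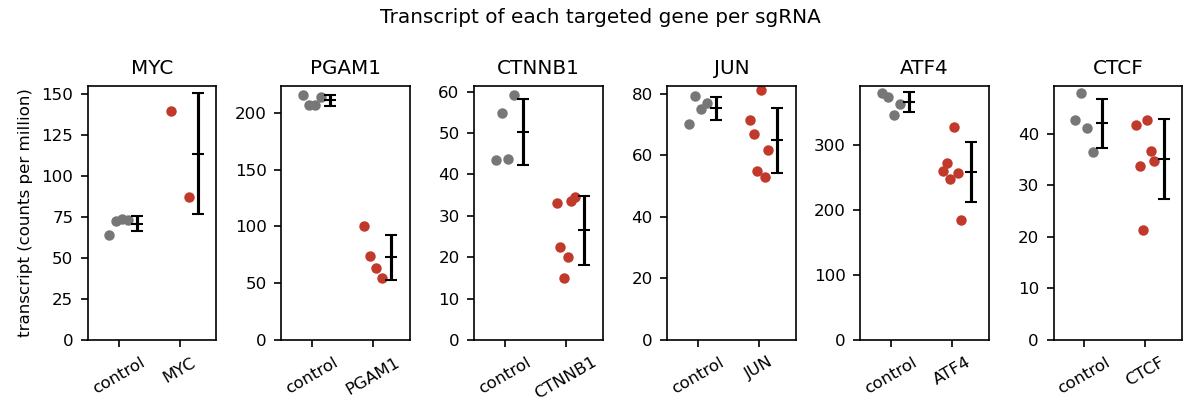
Level of each targeted transcript, in CPM, for each sgRNA (1 point per sgRNA, grey for the control sgRNAs and red for the sgRNAs of the gene named above the panel), with the mean and SD as bars. All 4 PGAM1 sgRNAs lie between 54.1 and 99.87, below every control, whereas both MYC sgRNAs lie above every control.

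With ATF4 sgRNAs, integrated stress response targets were lower as a group, and single genes of amino acid synthesis were lower. Of the 11570 genes tested, 203 changed, 70 higher and 133 lower, and 198 of them moved the same way in all 6 sgRNAs. In the list of ATF4 and integrated stress response targets, 19 of 40 tested members fell and none rose (29 lower and 0 higher when adjusted over the list alone). Its median log2 fold change was -0.31 (camera adjusted p = 2.1e-45, and adjusted p = 1.3e-05 with an estimated correlation). The serine synthesis enzymes PSAT1 (-0.56 ± 0.059, edgeR adjusted p = 1.5e-10; 167 ± 15.2 against 248 ± 5.29 CPM) and PHGDH (-0.46 ± 0.057, adjusted p = 2.7e-08) fell, as did CTH of cysteine synthesis (-1.23) and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase (-0.61). The stress genes NUPR1 (-1.29 ± 0.20, adjusted p = 1.1e-05), CHAC1 (-0.94) and DDIT4, an inhibitor of mTORC1 (-0.81 ± 0.099, adjusted p = 2.0e-08), fell too. The strongest decrease among the named genes was in CAMP, which encodes the antimicrobial peptide cathelicidin, at 4.12 ± 1.73 CPM against 20.5 ± 3.24 CPM (4.64-fold lower, adjusted p = 7.8e-11). ECM2 (-1.41), LINC01133 (-1.37), PIP5KL1 (-1.03), TIMP4 (-1.01), RHBDL1 (-0.90) and SLC16A4 (-0.82) fell as well. The gene with the smallest p, named after its values were seen, was S100P, a calcium-binding protein (-0.65 ± 0.056, adjusted p = 3.9e-14).

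Other groups moved with the ATF4 sgRNAs. Among NRF2 targets and pentose phosphate genes, 6 of 16 fell (10 lower when adjusted over the list alone; median -0.26, adjusted p = 0.0024 with an estimated correlation). They included the aldo-keto reductases AKR1C1 (-0.55), AKR1C3 (-0.33) and AKR1B10 (-0.34) and the transketolase TKT (-0.34). Of 10 heat shock genes, 2 fell, the chaperones HSPA8 (-0.52 ± 0.060, edgeR adjusted p = 4.4e-09) and HSPA1A (-0.50), and 6 were lower when adjusted over the list alone (median -0.12, adjusted p = 0.020 with an estimated correlation, and 0.093 without control sgRNA 4). Of 18 targets of the endoplasmic reticulum stress factors ATF6 and XBP1, 3 fell: HERPUD1 (-0.62), XBP1 (-0.32) and the chaperone HSPA5 (-0.32). The same 3 were the count adjusted over the list alone (camera adjusted p = 0.0030, and adjusted p = 0.071 with an estimated correlation). Of 35 MYC targets of ribosome biogenesis and growth, 5 rose (14 higher and 1 lower when adjusted over the list alone; camera adjusted p = 3.5e-07, and adjusted p = 0.071 with an estimated correlation). Among them were ODC1, the first enzyme of polyamine synthesis (0.38), PA2G4 (0.25), NME1 (0.23) and the nucleolar gene MYBBP1A (0.71). Of 11 hypoxia genes, EGLN3 (-0.92) and VEGFA (-0.47) fell (5 lower when adjusted over the list alone; camera adjusted p = 0.0032, and adjusted p = 0.21 with an estimated correlation). Of 11 epithelial genes, the keratins KRT19 (-0.22) and KRT8 (-0.19) fell (6 lower when adjusted over the list alone; camera adjusted p = 0.0097, and 0.22 without control sgRNA 4; adjusted p = 0.35 with an estimated correlation). The glutamine transporter SLC1A5 (-0.48), LCN2 (-0.42) and IFI27 (-0.44) fell, and KLF6 (0.41) and NDUFS6 (0.18) rose, without a call for their lists. Control sgRNA 4 had 295 CPM of IFI27 (nearest control 183) and 634 CPM of NDUFS6 (nearest 780.0), and without it neither gene passed (edgeR adjusted p = 0.30 and 0.27). The largest increases were in AC010327.4 (0.98), ANKRD1 (0.79), TAF1A (0.65), FAM24B (0.61), RASAL2 (0.56), GPATCH4 (0.52), PHACTR2 (0.49), PHKG2 (0.48), SNHG5 (0.45), TSPAN4 (0.44) and LENG1 (0.44). The count of 203 was 133 without control sgRNA 1, 94 under the stricter sgRNA rule, 64 in cells with at most 10% mitochondrial UMIs, 112 in G1-scored cells and 308 when the ATF4 and control sgRNAs were fitted alone.

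With PGAM1 sgRNAs, immediate early genes, keratins and mitochondrially encoded genes were lower. Of 11570 genes, 45 changed, 10 higher and 35 lower, and 44 moved the same way in all 4 sgRNAs. Transcription factors induced within minutes by growth signals fell. FOS stood at 30.01 ± 5.74 CPM against 99.3 ± 20.9 CPM (3.43-fold lower, log2 -1.78 ± 0.16, edgeR adjusted p = 5.5e-13), and FOSB (-1.45), EGR1 (-1.12) and KLF6 (-0.72) fell too. These were the 4 of 14 immediate early genes that fell (6 lower when adjusted over the list alone; median -0.20, adjusted p = 3.1e-05 with an estimated correlation). Of 11 epithelial genes, 3 fell, the keratins KRT19 (-0.57 ± 0.054, adjusted p = 1.6e-12; 1557 against 2328 CPM), KRT8 (-0.40) and KRT18 (-0.32), and 6 were lower when adjusted over the list alone (adjusted p = 0.00031 with an estimated correlation). Of the 13 mitochondrially encoded genes, 5 fell (9 lower when adjusted over the list alone; median -0.19, adjusted p = 0.012 with an estimated correlation), among them MT-CYB (-0.32), MT-CO2 (-0.29), MT-ND5 (-0.37) and MT-CO1 (-0.19). The median share of mitochondrial UMIs was 9.71% in these cells and 11.2% in control cells. These 4 genes lost their call in cells with at most 10% mitochondrial UMIs, a filter that acts on their own counts.

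Of 16 NRF2 targets and pentose phosphate genes, 4 fell with PGAM1 sgRNAs, all aldo-keto reductases: AKR1B10 (-0.72), AKR1C1 (-0.61), AKR1C2 (-0.35) and AKR1C3 (-0.25). The list had 6 lower genes when adjusted over the list alone (adjusted p = 0.014 with an estimated correlation, and 0.051 without control sgRNA 1). Of 15 glycolysis genes, PGAM1 itself was the 1 that fell, and 2 were lower when adjusted over the list alone. The list was called with an estimated correlation when it held PGAM1 (median -0.14, adjusted p = 0.0035) and not without PGAM1 (14 genes, median -0.12, adjusted p = 0.28; camera adjusted p = 0.0047), a test chosen after seeing the data. No single cholesterol synthesis gene of 16 passed, over all genes or when adjusted over the list alone, and the list as a group was lower (median -0.17, adjusted p = 0.034 with an estimated correlation). Without control sgRNA 1, 3 or 4 that call was lost (adjusted p = 0.052, 0.069 and 0.052). Lists called with the preset correlation alone were G2/M genes (52 tested, 14 higher when adjusted over the list alone, median 0.23, adjusted p = 0.35 with an estimated correlation), G1/S genes (median 0.13, adjusted p = 0.45), fatty acid synthesis (median -0.29, adjusted p = 0.24), NF-kB targets (median 0.22, adjusted p = 0.49), integrated stress response targets (median 0.05, adjusted p = 0.51) and interferon genes (median 0.14, adjusted p = 0.63). Further decreases were in B3GALT6 (-1.03), IRX3 (-0.99), the ephrin receptor EPHA4 (-0.89), PSCA (-0.83), CAPS (-0.78) and NDUFB9 of respiratory complex I (-0.28). Increases were in AHI1 (0.83), the stress gene NUPR1 (0.80), ANXA3 (0.64), GNG11 (0.59), CFAP20 (0.58), LMO4 (0.53), the metallothionein MT2A (0.46), STMN1 (0.40) and TXNIP (0.35). The count of 45 was 19 without control sgRNA 1, 28 without control sgRNA 3 and 21 without PGAM1 sgRNA 3. It was 91 with no filter on low counts, 26 under the stricter sgRNA rule, 21 in cells with at most 10% mitochondrial UMIs, 19 in G1-scored cells and 76 when the PGAM1 and control sgRNAs were fitted alone.

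In cells labelled with MYC sgRNAs, whose MYC transcript was not lower, interferon-induced genes were higher and several genes of translation were lower, fewer of them with another scaling. Of 11570 genes, 32 changed, 19 higher and 13 lower, in 2 sgRNAs against 4 controls. All 4 MYC sgRNAs had a higher share of G1-scored cells than the controls (66.7 to 75% against 53.2 to 61.6%) and a lower median depth (9654 to 10342.5 against 12000 to 12656 UMIs). With DESeq2's size factors in place of TMM the split was 23 higher and 6 lower. IFI6 stood at 221 ± 41.3 CPM against 91.8 ± 24.8 CPM (log2 1.30 ± 0.22, edgeR adjusted p = 0.00035), and IFI27 (1.13 ± 0.20, adjusted p = 0.00096) and OAS2 (2.19, adjusted p = 0.0078) rose too. Of 13 interferon genes in the fixed list, 2 rose (6 higher when adjusted over the list alone; median 0.55, camera adjusted p = 5.1e-16, and adjusted p = 0.016 with an estimated correlation). The self-contained test fry did not call this list (adjusted p = 0.062). PAPPA (2.19), SDCBP2 (1.68), the adhesion molecule CEACAM6 (1.04), PSCA (0.82), the tetraspanin CD151 (0.67), MT2A (0.53), the growth factor MDK (0.52) and AKR1B10 (0.50) rose as well. PSCA and CEACAM6 were also among the leading genes of cluster 7, in which 95.1% of cells were scored as G1. THUMPD3-AS1 (0.63) was called, with 26.6% of its UMIs in 1 cell. Also called was AL137800.1, named after its values were seen, with 92.6% of its UMIs in 1 cell.

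The decreases with MYC sgRNAs were GAL, which encodes the neuropeptide galanin, at 20.1 ± 7.89 CPM against 62.2 ± 3.36 CPM (3.31-fold lower, edgeR adjusted p = 0.0020), and smaller ones in CHCHD10 (-0.37), the chaperonin HSPD1 (-0.36), LDHB (-0.35), the initiation factor subunit EIF3E (-0.30) and YBX1 (-0.27). The ribosomal protein genes RPL4 (-0.36), RPS24 (-0.28), RPL3 (-0.24), RPS18 (-0.23), RPS2 (-0.23) and RPL12 (-0.23) completed them, with ZBED3-AS1, named after its values were seen, which had no UMI in the MYC sgRNAs. With DESeq2's size factors, GAL, HSPD1, RPL4, RPS24 and RPS2 were the named decreases that passed. Of 35 MYC targets of ribosome biogenesis and growth, HSPD1 fell (2 lower when adjusted over the list alone; median -0.22, camera adjusted p = 0.00026, and adjusted p = 0.24 with an estimated correlation). Epithelial genes (4 higher when adjusted over the list alone, median 0.16, adjusted p = 0.11 with an estimated correlation), NRF2 targets (median 0.10, adjusted p = 0.37) and NF-kB targets (median 0.27, adjusted p = 0.45) were called with the preset correlation alone. The count of 32 was 18, 19 and 20 without control sgRNAs 1, 2 and 3, 4 without MYC sgRNA 2 and 8 without MYC sgRNA 4, where the lone sgRNA is assumed to vary like the others. It was 83 with DESeq2, 92 under the looser sgRNA rule, 1 under the stricter rule and 4 in G1-scored cells (1 MYC sgRNA each), and 51 when the MYC and control sgRNAs were fitted alone.

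**Figure D2:**
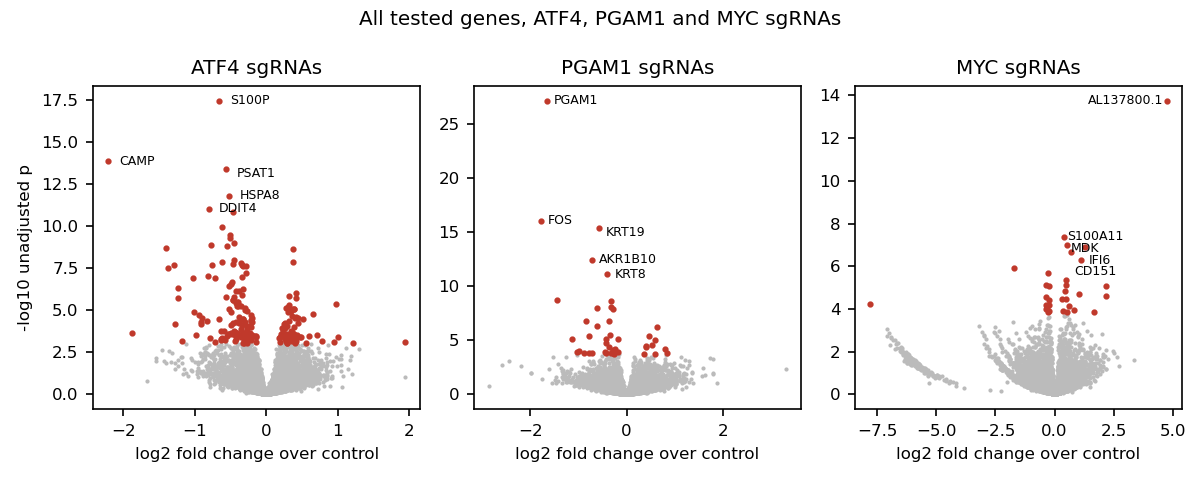
Log2 fold change against the control sgRNAs (horizontal axis) and -log10 of the unadjusted p (vertical axis) of each of the 11570 tested genes for ATF4, PGAM1 and MYC sgRNAs. Red points passed the adjusted threshold (203, 45 and 32 genes), the 5 genes with the smallest p are labelled, and the streaks at the left of the MYC panel are genes with few or no counts in the MYC sgRNAs.

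With CTNNB1 sgRNAs, 1 gene of 11570 passed with edgeR, CTNNB1 itself, and 1 passed with DESeq2, while 498 had an unadjusted p under 0.05. IGFBP3, a binding protein of insulin-like growth factors (-0.81, adjusted p = 0.061), and the interferon-induced IFI27 (-0.53, adjusted p = 0.079) and IFI6 (-0.49, adjusted p = 0.24) had values below the controls in 6 of 6 sgRNAs without passing. So had MARCH9 (-0.67), KCNQ1OT1 (-0.25) and SLC37A4 (-0.79), and CFAP20 (0.36), KLK7 (0.66) and POLR3K (0.36) had values above. In the interferon list, 0 of 13 members passed over all genes and 7 were lower when adjusted over the list alone (median -0.30, camera adjusted p = 1.0e-12, and adjusted p = 0.034 with an estimated correlation, while fry gave adjusted p = 0.13). Control sgRNA 4 had 295 CPM of IFI27 (nearest control 183). Without it the list had a median of -0.22 (camera adjusted p = 5.7e-07, and adjusted p = 0.19 with an estimated correlation). The call with an estimated correlation was also lost without control sgRNA 1 or 3 (adjusted p = 0.052 and 0.065). Of 11 tested Wnt and beta-catenin targets, 0 passed, over all genes or when adjusted over the list alone (median -0.05, camera adjusted p = 0.26). MYC targets (median 0.07, adjusted p = 0.24 with an estimated correlation), G1/S genes (median 0.11, adjusted p = 0.36), G2/M genes (median 0.09, adjusted p = 0.66), hypoxia genes (median -0.08, adjusted p = 0.42) and nuclear oxidative phosphorylation (median 0.01, adjusted p = 0.56) were called with the preset correlation alone. The count was 2 without control sgRNA 1, 2 under the stricter sgRNA rule, 5 with no filter on low counts, 6 when fitted alone with the controls, and 0 in cells with at most 10% mitochondrial UMIs and in G1-scored cells.

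With JUN sgRNAs, 1 gene passed with edgeR and 0 with DESeq2, while 536 had an unadjusted p under 0.05. The gene was PI3, which encodes the elastase inhibitor elafin, at 104 ± 30.8 CPM against 54.6 ± 14.5 CPM (log2 0.95 ± 0.16, adjusted p = 0.0015; higher in 6 of 6 sgRNAs). The cytokine IL11 (-0.64, adjusted p = 0.18), the mitotic genes CCNB1 (0.39, adjusted p = 0.18), KIF18A (0.77, adjusted p = 0.23) and CENPF (0.44, adjusted p = 0.45), and MARCH9 (-0.70), IFT22 (0.36), G3BP2 (-0.29), CYP1B1 (0.32) and SAA1 (0.85) had the next smallest p and did not pass. Of 28 JUN and AP-1 targets, 0 passed over all genes and 1 was lower when adjusted over the list alone (median -0.09, camera adjusted p = 0.00043, and adjusted p = 0.11 with an estimated correlation). G2/M genes (2 higher when adjusted over the list alone, median 0.19, camera adjusted p = 9.0e-15, and adjusted p = 0.24 with an estimated correlation) and epithelial genes (median -0.07, adjusted p = 0.35 with an estimated correlation) were called with the preset correlation alone. The count of 1 was 0 without control sgRNA 1 or 2, 2 without control sgRNA 4 and 3 without JUN sgRNA 6. It was 0 under the looser and stricter sgRNA rules, in cells with at most 10% mitochondrial UMIs and in G1-scored cells, 15 with no filter on low counts and 4 when fitted alone with the controls.

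With CTCF sgRNAs, 3 genes passed with edgeR and 0 with DESeq2, while 721 had an unadjusted p under 0.05. TTYH1, a membrane protein of the tweety family, stood at 47.5 ± 31.5 CPM against 19.7 ± 2.48 CPM (log2 1.01 ± 0.18, adjusted p = 0.0060). STAG1, a cohesin subunit, stood at 28.2 ± 18.5 CPM against 10.6 ± 3.45 CPM (log2 1.12 ± 0.22, adjusted p = 0.012). The elongation factor EEF1A2 was lower (-0.37 ± 0.079, adjusted p = 0.041), and all 3 genes moved the same way in 6 of 6 sgRNAs. CTCF sgRNA 3 had the highest level of both higher genes, 109.6 CPM of TTYH1 and 63.8 CPM of STAG1. SYCE3 (3.19), AKR1C1 (0.32), PCOTH (3.41), NMB (-0.38), MALAT1 (0.25), GNG10 (0.29) and NEAT1 (0.37) had the next smallest p and did not pass. G2/M genes (median 0.06, adjusted p = 0.75 with an estimated correlation) and interferon genes (median -0.04, adjusted p = 0.59) were called with the preset correlation alone, and no member of either passed when adjusted over the list alone. The count of 3 was 0 without control sgRNA 1, 1 without control sgRNA 2, 24, 0, 6, 8 and 12 without CTCF sgRNAs 1, 2, 3, 5 and 6, 37 with no filter on low counts, 8 in G1-scored cells, 1 without the cells of the hypoxia cluster (an alternative chosen after seeing the data), and 0 under the stricter sgRNA rule, in cells with at most 10% mitochondrial UMIs and when fitted alone with the controls.

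**Figure D3:**
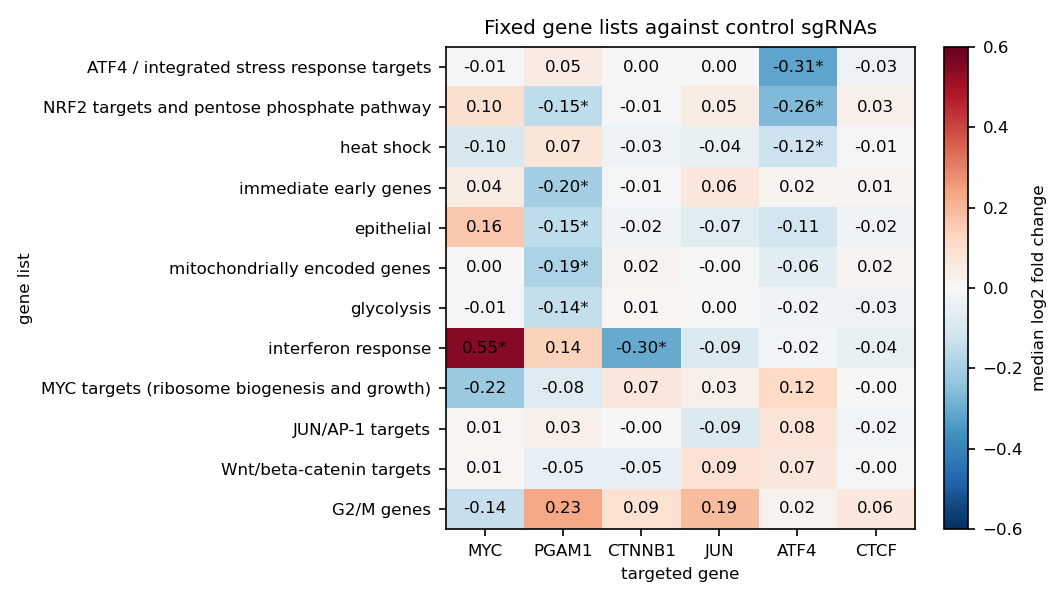
Median log2 fold change of 12 fixed gene lists (rows) against the control sgRNAs, for the sgRNAs of each targeted gene (columns), with the value in each field and on the colour scale. An asterisk marks an adjusted p under 0.05 with an estimated correlation, as for integrated stress response targets with ATF4 (-0.31) and interferon genes with MYC (0.55) and CTNNB1 (-0.30). That of glycolysis genes with PGAM1 was lost without PGAM1 itself, a member of the list, and that of interferon genes with CTNNB1 was lost without control sgRNA 4.

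The targets were also compared with each other. ATF4 and PGAM1 sgRNAs differed in 349 genes, 170 higher and 179 lower with ATF4 sgRNAs. NUPR1 (log2 difference, ATF4 minus PGAM1, -2.09 ± 0.21, edgeR adjusted p = 1.2e-11) and PSAT1 (-0.68 ± 0.065, adjusted p = 2.7e-12) were lower with ATF4 sgRNAs. FOS (1.62 ± 0.16, adjusted p = 5.2e-12), KLF6 (1.13 ± 0.16, adjusted p = 1.2e-06) and KRT19 (0.36 ± 0.051, adjusted p = 8.8e-07) were lower with PGAM1 sgRNAs. Both sets lowered AKR1B10, more so with PGAM1 sgRNAs (difference 0.38 ± 0.078, adjusted p = 0.00085). In all, 9 genes were called in the same direction in both comparisons (AKR1B10, AKR1C1, AKR1C3, CAPS, CSTB, GPX2, KRT19, KRT8 and PSCA) and 3 in opposite directions (KLF6, LMO4 and NUPR1). Both comparisons use the same 4 control sgRNAs. Independent calls would share 0.463 genes in the same direction. In 20 simulated sets with shared controls and no effect, 0 were shared. Sets without an effect hold few calls by design, so that 0 does not say how many of the 9 arise from the shared controls. With the controls divided between the comparisons, 3 to 5 were shared. Over 5494 genes the ATF4 and PGAM1 fold changes had a correlation of 0.242, against 0.445 in the simulated sets and 0.021 with the controls divided. Their covariance (0.00686) was within 1 SD of the simulated value (0.00659 ± 0.00028), so a shared change beyond the named genes was not detectable. MYC and PGAM1 sgRNAs differed in 84 genes, and AKR1B10 (PGAM1 minus MYC, -1.22 ± 0.12, adjusted p = 2.4e-11), KRT19 (-0.82, adjusted p = 5.7e-14) and IFI6 (-1.25) were higher with MYC sgRNAs. MYC and ATF4 sgRNAs differed in 144 genes, among them IFI27 (ATF4 minus MYC, -1.56, adjusted p = 2.9e-07). ATF4 and MYC calls shared RPL3 in the same direction and AKR1B10, IFI27, PSCA and SRGN in opposite directions, and PGAM1 and MYC calls shared MT2A in the same direction and AKR1B10 and PSCA in opposite directions. The covariance of ATF4 and MYC fold changes, -0.00082, lay below the simulated value for shared controls (0.00676 ± 0.00042). With the controls divided their correlation was -0.12. For PGAM1 and MYC the covariance was 0.0045 (simulated 0.0067 ± 0.00063) and the correlation with the controls divided -0.032. The cause of these lower values was not tested. ATF4 and CTCF sgRNAs differed in 681 genes, ATF4 and JUN sgRNAs in 389, ATF4 and CTNNB1 sgRNAs in 238, PGAM1 and CTCF sgRNAs in 124, and the remaining pairs in 12 (CTNNB1 and JUN) to 96 (PGAM1 and CTNNB1).

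The cells as a whole were epithelial. All 11 epithelial genes stood at 10 CPM or more, led by KRT18 at 4435 CPM, against 1 of 8 mesenchymal genes (FN1, 29.8 CPM), 1 of 9 immune genes (CD68, 19.5 CPM), and 0 of the alveolar type 2 (10 genes), basal or squamous (7), neuroendocrine (6), fibroblast (7), endothelial (6) and erythroid (4) genes. Of the targeted genes, ATF4 had the highest level over all cells, 344 CPM (exact 95% Poisson interval 340.9 to 347), followed by PGAM1 (205 CPM), MYC (76.1 CPM), JUN (72.9 CPM), CTNNB1 (42.9 CPM) and CTCF (38.5 CPM). The JUN relatives JUND (132 CPM) and JUNB (116 CPM) were above JUN, and their partner FOS stood at 90.4 CPM. The catenins CTNND1 (59.6 CPM) and JUP (46.6 CPM) were above CTNNB1 over all cells. These pooled levels include cells whose sgRNAs lowered the gene. With control sgRNAs CTNNB1 stood at 50.3 CPM, a mean over sgRNAs with TMM scaling that is not the same measure. It lay above the pooled level of JUP, so the order of these 2 in control cells is left open. MYCN had 0 UMIs, which allows up to 0.0276 CPM, and MYCL stood at 0.569 CPM.

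The cells fell into 10 clusters. Clusters 0 (14.5% of cells), 1 (8.80%), 2 (11.7%) and 3 (6.32%) were led by genes of DNA replication and mitosis, such as HIST1H1D and CLSPN in cluster 0 (5.96-fold and 5.01-fold above the other cells), AURKA and ASPM in cluster 1 (10.2-fold and 9.59-fold), CDT1 and CDK1 in cluster 2 (2.10-fold and 2.06-fold) and PTTG1 and CDC20 in cluster 3 (3.68-fold and 3.31-fold). By their scores, 58.1% of cells were in G1, 13.8% in S and 28.1% in G2 or M, calls that free RNA and depth can move. Cluster 4, with 5.69% of cells (exact 95% binomial interval 5.25 to 6.16%), was led by the hypoxia genes IGFBP3 (18.8-fold), EGLN3 (9.69-fold), TMEM45A (9.64-fold) and NDRG1 (9.55-fold). All 12 genes of the hypoxia list were higher in it (median log2 fold 1.75, above all random lists). Clusters 6 (19.8%) and 7 (17.0%) lay apart from each other on NF-kB targets, with median log2 folds of 0.39 and -1.75. Cluster 0 also had high NF-kB targets (0.49). Cluster 6 was led by genes such as INHBA (2.01-fold) and the chemokine CXCL8 (1.76-fold), and cluster 7 by PSCA (2.14-fold) and CEACAM6 (2.08-fold). Cluster 5 (10.4%) was led by S100A9 (1.71-fold) and cluster 8 (2.32%), of low depth (median 6604 UMIs), by C1orf56 (7.86-fold). Cells holding sgRNAs of several targets made up 26.7% of cluster 2, which had 6.31% mitochondrial UMIs, 25.5% of cluster 8 and 4.34 to 9.18% of the other clusters. Cluster 9, with 346 cells (3.41%), stood apart, with FABP5 (316-fold), MT1E (180-fold), UBE2M (149-fold) and GTSF1 (145-fold) at most at 0.694 CPM in the other cells, and an sgRNA was assigned to 13.3% of its cells. Whether its cells are PC9, a subclone or another line was not tested.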

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

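The tests of cell cycle phase and mitochondrial share with PGAM1 sgRNAs, of MYC sgRNAs 1 and 3 and of control cells matched to the MYC cells, and both tests of the CTCF sgRNAs were chosen after the results were seen.

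With PGAM1 sgRNAs, immediate early genes, keratins and mitochondrially encoded genes were lower, and these cells had a lower median share of mitochondrial UMIs (9.71% against 11.2%). A shift in cell cycle phase as the whole cause is argued against by G1-scored cells. In these the median log2 fold change of 34 lower genes was -0.381, or 89.8% of that in all cells of the same 3 PGAM1 sgRNAs. The 95% interval, 78.6 to 105%, came from resampling these genes, which were called in the same cells. It does not cover the spread between sgRNAs. A difference in mitochondrial share as the whole cause is argued against, for the 29 nuclear genes, by cells with at most 10% mitochondrial UMIs. There their median was -0.602, or 136% (95% interval over genes 85.1 to 155%) of that in all cells of the same 3 sgRNAs. The mitochondrially encoded genes are not covered by that test, since the filter acts on their own counts. G1-scored cells also fell into different clusters. Cluster 7, with the lower genes PSCA, CAPS and IGFBP2 among its leading genes, held 13.2% of PGAM1 cells (interval 9.77 to 17.3%). It held 19.6% of control cells (interval 16.7 to 22.7%). Whether a difference in cluster shares plays a part was not tested. Loss of PGAM1 and unintended targets of its sgRNAs both remain open, and neither was tested.

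In cells labelled with MYC sgRNAs, 19 genes were higher, interferon-induced genes among them, although the MYC transcript was not lower. A few cells with many UMIs as the whole cause is argued against: without the top cell of each sgRNA, 2 of the 19 genes kept under 50% of their log2 ratio, and the median went from 0.65 to 0.49. An effect confined to the tested sgRNAs is argued against by the 26 cells of MYC sgRNAs 1 and 3, left out of the test, where the median log2 ratio of the 19 genes against cells of the other targets was 0.548 (random lists -0.117 to 0.223), with 19 of 19 above 0. The higher G1 share and lower depth of MYC cells as the whole cause are argued against by control cells matched in phase and UMIs. Against these the median was 0.658, or 100.9% (interval over genes 73.1 to 126%) of that against all control cells. The 19 genes were called in the same MYC cells against the same controls, so part of the retained ratio may follow from that choice. The interval does not cover the spread between sgRNAs. Matching used phase and UMIs alone, so differences in clusters among G1-scored cells were not covered. Whether the higher level of the 19 genes follows from MYC stays open and was not tested. The same holds for selection among the few cells with these sgRNAs, 1.69% of those assigned.

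CTCF sgRNA 3 stood apart from the other CTCF sgRNAs, with 43.8% of its 48 cells in the hypoxia cluster (next highest 15.7%), 109.6 CPM of TTYH1 (next 50.1) and 63.8 CPM of STAG1 (next 31.5). Over all 6 CTCF sgRNAs the share in that cluster was 14.8 ± 14.7% against 5.44 ± 1.77% in the controls (two-sided exact permutation p = 0.219). Without sgRNA 3 it was 9.06 ± 4.50% (two-sided exact permutation p = 0.175), so whether the higher share is that of sgRNA 3 alone cannot be told apart with 5 against 4 sgRNAs. Across the 6 sgRNAs, the CTCF transcript and the share had Spearman's rho = -0.486 (exact permutation p = 0.356, adjusted 0.356) and Pearson's r = -0.876 (p = 0.0639, adjusted 0.128), 1 of 2 relations computed, and r = -0.505 without the 2 sgRNAs farthest from the median. The extent of CTCF loss therefore stays open, as does a single clone or an unintended target of sgRNA 3, which were not tested. The calls of TTYH1, STAG1 and EEF1A2 with CTCF sgRNAs did not rest on sgRNA 3. They held without it and were lost without sgRNA 2.

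Single sgRNAs lay far from the others of their group in 18 of 212 groups, where chance gives about 5% if all sgRNAs of a group vary alike. They need not, since their numbers of cells differ: control sgRNA 4 had 77 cells and control sgRNA 1 had 300. Among the control sgRNAs, sgRNA 1 had 63.8 CPM of MYC (others 72.7 to 73.4), sgRNA 3 had 747 CPM of AKR1C3 (nearest 800.2), and sgRNA 4 had 295 CPM of IFI27 (nearest 183), 24.6 CPM of IRX3 (18.8), 107 CPM of HERPUD1 (83.7), 634 CPM of NDUFS6 (780.0) and 159 CPM of HSPA1A (102). PGAM1 sgRNA 1 had 7.83 CPM of EPHA4 (nearest 15.01), 166 CPM of AKR1B10 (211) and 31.3 CPM of KLF6 (22.0), and PGAM1 sgRNA 3 had 227 CPM of TXNIP (193). ATF4 sgRNA 4 had 24.3 CPM of MYBBP1A (nearest 18.5) and ATF4 sgRNA 1 had 74.3 CPM of KLF6 (51.7). The median mitochondrial share was 8.52% with PGAM1 sgRNA 2 (nearest 9.86%) and 9.59% with JUN sgRNA 5 (10.9%). The remaining 3 were those of CTCF sgRNA 3. In the 761 cells that held sgRNAs of 2 targets and were assigned to none, outside the comparisons, PGAM1 stood at 113 CPM where 1 of the sgRNAs was against PGAM1 and at 224 CPM where none was.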

How the results depend on the processing

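The alternatives without the cluster that stands apart, without the hypoxia cluster, with sgRNAs of at least 10 cells and with bias-adjusted deviances, the list tests without the targeted gene or a control sgRNA, and the ribosomal protein test with DESeq2's size factors were chosen after seeing the data. For the changes below the cause was not tested, except that the stricter sgRNA rule, the limit of 10% mitochondrial UMIs and G1-scored cells leave fewer cells. Genes changed with MYC sgRNAs (32) numbered 83 with DESeq2, 92 under the looser sgRNA rule, 1 under the stricter rule, 4 in G1-scored cells, 51 when fitted with the controls alone and 55 with sgRNAs of at least 10 cells. Those with PGAM1 sgRNAs (45) numbered 91 with no filter on low counts, 26 under the stricter rule, 21 at 10% mitochondrial UMIs, 19 in G1-scored cells and 76 with the controls alone. Those with ATF4 sgRNAs (203) numbered 94, 64, 112 and 308 under the stricter rule, at 10% mitochondrial UMIs, in G1-scored cells and with the controls alone. Those with CTNNB1 sgRNAs (1) numbered 5 with no filter, 2 under the stricter rule, 0 at 10% mitochondrial UMIs, 0 in G1-scored cells, 6 with the controls alone and 3 without the cluster that stands apart. Those with JUN sgRNAs (1) numbered 0 with DESeq2, 15 with no filter, 0 under the looser and the stricter rule, at 10% mitochondrial UMIs and in G1-scored cells, and 4 with the controls alone. Those with CTCF sgRNAs (3) numbered 0 with DESeq2, 37 with no filter, 0 under the stricter rule, at 10% mitochondrial UMIs and with the controls alone, 8 in G1-scored cells, 1 without the hypoxia cluster and 5 with bias-adjusted deviances.

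Leaving out each sgRNA in turn gave 4 to 39 genes for MYC, where a lone MYC sgRNA is assumed to vary like the others, with 18, 19 and 20 without control sgRNAs 1, 2 and 3, 4 without MYC sgRNA 2 and 8 without MYC sgRNA 4. For PGAM1 it gave 19 to 36, with 19 without control sgRNA 1, 28 without control sgRNA 3 and 21 without PGAM1 sgRNA 3. For ATF4 it gave 133 (without control sgRNA 1) to 234, and for CTNNB1 1 to 2 (without control sgRNA 1). For JUN it gave 0 to 3, with 0 without control sgRNA 1 or 2, 2 without control sgRNA 4 and 3 without JUN sgRNA 6. For CTCF it gave 0 to 24, with 0 and 1 without control sgRNAs 1 and 2, and 24, 0, 6, 8 and 12 without CTCF sgRNAs 1, 2, 3, 5 and 6. The targeted transcripts kept their call and sign in these fits, with log2 fold changes of -0.63 to -0.41 (ATF4), -0.23 to -0.12 (CTCF), -1.09 to -0.78 (CTNNB1), -0.22 to -0.11 (JUN), 0.33 to 0.99 (MYC) and -1.77 to -1.51 (PGAM1). The CTNNB1 transcript lost its call under the stricter rule (-0.76), at 10% mitochondrial UMIs (-0.82) and in G1-scored cells (-0.79). The sign turned for the JUN transcript at 10% mitochondrial UMIs (0.065), the CTCF transcript in G1-scored cells (0.24) and THUMPD3-AS1 with MYC sgRNAs under the stricter rule (-0.014). Pairs of list and target past the threshold numbered 35 with the preset correlation, 11 with an estimated correlation and 12 with fry, and 36, 40, 37 and 35 with the preset correlation without control sgRNAs 1, 2, 3 and 4.

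For named genes, 1362 of the values under the other settings kept their side of the threshold, 242 lost it, 30 gained it and 1 reversed, and with an sgRNA left out 875 kept it, 251 lost it and 24 gained it. The cell shares that moved were those of MYC (1.33%), PGAM1 (5.25%) and ATF4 (14.3%) under the stricter rule. S and G2 or M shares were 11.4% and 31.2% in thinned cells and 11.4% and 32.5% with no cell filter, where G1 was 56.1%. There were 17 clusters at resolution 1.0, and the hypoxia list in cluster 4 had a median of 1.96 in thinned cells. Family levels moved in 50 comparisons and stayed within their intervals in 82. No paired analysis was possible because the sgRNAs of different targets have no partners. A block for the barcode suffix was not run, since there was 1 suffix, nor was co-expression, since sgRNAs were read, and leaving out Scrublet's doublets says nothing, since it marked 1 cell. MYC had no value at 10% mitochondrial UMIs, where no MYC sgRNA had 20 cells. MYC, with 2 sgRNAs and 68 cells, had the lowest recovery in simulated counts (37% of genes changed 2-fold), in which depth and number of sgRNAs were not varied apart.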

Other observations

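The tests of ribosomal protein genes, with both scalings, and of the MYC sgRNAs with few cells were chosen after the results were seen. With TMM scaling, ribosomal protein genes were lower as a group in cells labelled with MYC sgRNAs, whose MYC transcript was not lower. Of 78 such genes, 71 had a log2 fold change below 0 and 6 fell, with a median of -0.12 (camera adjusted p = 0.0292 with an estimated correlation), where the median of all genes was -0.044. With DESeq2's size factors, 71 were below 0 and 3 fell, the medians were -0.086 and -0.014, and the group was not called (camera adjusted p = 0.14 with an estimated correlation). With the other targets and TMM scaling the camera adjusted p with an estimated correlation was 0.49 to 0.89. With those size factors, 68 of the 78 genes lay below the median of all genes. The group therefore lay below the other genes with both scalings, whereas its call depended on the scaling. Whether the shift goes beyond the spread between sgRNAs stays open.

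The cluster led by hypoxia genes, cluster 4, also had higher glycolysis genes (median log2 fold 0.58), interferon genes (0.78) and epithelial genes (0.61), and lower integrated stress response targets (-0.56) and MYC targets (-0.48) than the other cells. AGR2 (4.17-fold), KRT15 (3.86-fold) and the prolyl hydroxylase P4HA1 (5.53-fold) were among its leading genes, and 97.2% of its cells were scored as G1. Cluster 9, the one that stood apart, had higher Wnt and beta-catenin targets (0.91), G1/S genes (0.86), glutamine and aspartate genes (0.82), MYC targets (0.75) and p53 targets (0.51), and lower NRF2 targets (-0.85) and epithelial genes (-0.57). NPW (138-fold), MSX1 (93.1-fold), MAGEB2 (79.6-fold) and AKAP12 (55.0-fold) were among its leading genes, and 46 of its cells had an assigned sgRNA. In cluster 8, CTNNB1 stood at 129 CPM against 41.9 CPM in the other cells, with PHKG1 (7.40-fold) and LRRC75A (5.90-fold).

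Of the 854 cells holding sgRNAs of 2 targets, 761 were assigned to no sgRNA and so left out of the tests, and these gave a check on other cells of the same culture. The 133 genes lower with ATF4 sgRNAs had a median log2 ratio of -0.207 in 220 such cells with an ATF4 sgRNA against 541 without (121 of 133 below 0, random lists -0.0083 to 0.038), and the 70 higher genes 0.15 (62 above 0). The 35 genes lower with PGAM1 sgRNAs had a median of -0.193 in 110 such cells against 651 (30 below 0, random lists -0.047 to 0.0498), and the 10 higher genes 0.17 (8 above 0). For MYC, with 22 such cells, the 19 higher genes had a median of 0.19 (17 above 0) and the 13 lower genes -0.15 (11 below 0).

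It was asked whether ATF4 sgRNAs with less ATF4 transcript also lowered the integrated stress response list more. Across the 6 sgRNAs, Spearman's rho was -0.6 (exact permutation p = 0.242, adjusted 0.356) and Pearson's r was -0.478 (exact permutation p = 0.340, adjusted 0.340), 1 of 2 relations computed, and r was -0.0109 without the 2 sgRNAs farthest from the median. The relation asked about would give positive coefficients, and these were negative. With 6 sgRNAs the relation cannot be told apart from none.

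Other splits of each target's and the control sgRNAs were fitted in the same way. For PGAM1 these were all other splits. For ATF4, CTNNB1, JUN and CTCF they were a random draw, so a split not drawn could exceed the highest value given. For ATF4, 1 of 100 splits, the real one, gave 203 genes, the highest other gave 98, and chance can be excluded at 0.05. For PGAM1, 1 of 35 splits, the real one, gave 45 genes, the highest other gave 8, and chance can be excluded at 0.05. For CTNNB1, 6 of 100 splits gave as many as the real 1 gene, with 1 the highest other, and chance cannot be excluded for that count. The gene was CTNNB1 itself, at 15.1 to 34.6 CPM in the 6 CTNNB1 sgRNAs and 43.4 to 59.1 CPM in the 4 controls. For JUN, 11 of 100 splits gave as many as the real 1 gene, with 11 the highest other, and for CTCF, 13 of 100 gave as many as the real 3 genes, with 58 the highest other, so chance cannot be excluded for either. Highest values several times the real count point to a structure of the samples, whose source was not tested. With 2 sgRNAs, MYC was not split.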
